A study of Mus musculus with 18 samples.

How the data were processed

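The samples are 18 two-colour arrays of tail DNA from 9 mice of 1 family, with each animal in Cy5 on 1 array and in Cy3 on the other, against the DNA of reference male number 8 of the same colony. DNA was extracted with a tissue DNA protocol and labelled with an oligonucleotide array CGH protocol, per the labels' protocols. Groups (sire, dam, F1 progeny) came from the animal codes in the labels. The arrays lay on 5 slides, each scanned 1 time: slide 1 held the sire and the dam, slides 2 to 4 held 2 progeny each, and slide 5 held progeny 7.

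The intensity values of each spot are the processed red and green signals that the authors obtained from Feature Extraction 10.7.1.1, per the file headers. That software subtracted the background by spatial detrending and normalized the dyes linearly, per the file headers. Probe names carry positions on mm9 in the deposited files. The deposited series matrix holds log2 values, 1 column per array. Set against the scanner values of the same spots, each column was the reference over the animal (Pearson r of 0.981 or more across spots). The column medians ran from -0.006 to 0.015. The scale and direction are therefore known, and the centring and any further correction are not given in the sources used here. Between 99.56% and 99.88% of the spots were well above background in each channel, and no spot was saturated. Array signal over background limits the precision of the levels, and 18 arrays were used. No column was left without a sample (0 of them).

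Control spots and spots with an outlier flag (0.064% to 1.152% per array) were left out, and spots of a probe were averaged. Each array's log2 ratio of processed signals was centred on the median of the autosomal probes and turned to animal over reference. Both orientations were averaged, so the 2 arrays of an animal are 1 replicate. Arrays of the same orientation of different animals correlated between -0.08 and 0.72 across probes. No loess or quantile step was used. Tiled regions were runs of probes at most 10 kb apart, and those with at least 5 probes were counted.

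Calls came from an interval scan per animal. Each run of at least 3 probes in a tiled region was scored as the sum of its values over the robust probe noise times the square root of the probe number. A call had a score of at least 6, a mean of at least 0.25 in size, and in each orientation the same sign and a mean of at least 0.2 in size. Runs of up to 1500 probes were scanned. No p-value is given for calls, since each animal stands alone. False calls were counted in the difference of the orientations, in which copy number cancels and no orientation check applies, and in 3 shuffles of the probe order. A progeny call was absent from the parents when no parental call of the same direction shared a probe with it and its score against the mean of the parents was at least 6. Transmission was tested with a two-sided exact binomial test against 0.5 with Benjamini-Hochberg adjustment. Windows of 10 probes (at least 5) were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), and other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A bound for probes not well above background in the reference used the mean processed log2 signal of the animal over both arrays, against the reference's signal or, where higher, the lowest signal among probes well above background in that channel.

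The scan was tested on simulated data with 200 inserted segments on the array's own layout of 150921 probes. It found 64.7% of the 3-probe segments of 0.3, all segments of other sizes and lengths, and made 0 false calls under independent noise. A single noise level was simulated, whereas the probe noise of the animals ran from 0.043 (progeny 2) to 0.099 (progeny 7). The shares found need not hold for the noisier animals. In 14477 simulated windows limma found all shifts of 0.3 and 0.5 against the reference, 4% of those of 0.2 and 0% of those of 0.1. That test also requires a mean of at least 0.25 in size, which by itself holds back shifts of 0.1 and 0.2. These shares are therefore set mainly by that limit. For progeny against parents it found 52% of shifts of 0.1, 84% of 0.2, 88% of 0.3 and 96% of 0.5. It made 3 false calls there, against 0 in the test against the reference. The simulated windows had independent noise in each animal and no slide effect, whereas in the data the parents shared a slide without progeny. Apart from the inserted shifts they were centred on 0, and the largest spreads of the real windows were capped. These shares and false calls therefore leave out the slide, the most variable windows and any change of the variance with the mean. The shares found can be higher than they would be in the data.

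The tests, thresholds and alternatives were fixed before the data were examined, except where stated. Regions to name were those merged across animals: the 10 with the highest score in a progeny and no call in a parent, the 10 with the highest score called in a parent, and the 5 with the highest mean among those called in all 9 animals, of which there were 4. For windows the 5 with the smallest adjusted p per direction were named. Alternatives were normexp background correction (offset 50, on median spot and background signals, since the columns used hold medians), the series matrix values, centring on the mode or none, leaving out dim or saturated probes, each orientation alone, other score, length, size and gap limits, other overlap rules, other window lengths, the slide as a random block, array weights, no trend, and leaving out each animal. The planned overlap of calls with gene lists, and the part of the naming rule that uses genes, were not run. The annotation table used here is on GRCm38 while the probes are on mm9. The planned GC correction and the removal of probes with several matches need probe sequences, which were not used here.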

Results

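DNA copy number was measured in the tail DNA of 1 family of C57BL/6 mice: a sire, a dam and 7 of their F1 progeny. The series title gives the sire as a male kept under gamma rays at 1 mGy per day for 400 days, whereas the design text lists the same male as not irradiated. This conflict in the labels could not be settled here, so no value below is assigned to irradiation. The question the labels give is whether copy number changes appear in offspring that their parents did not carry. No family of a control male was analysed here, and the sire and the dam are 1 animal each. Each animal was hybridised 2 times, with the dyes exchanged, against the DNA of a single reference male of the same colony on a 2-colour tiling array built around candidate regions. The 18 arrays therefore stand for 9 animals. Values are log2 ratios of animal over reference, so that a gain is above 0. The spread given with a level is the SD of its 2 orientations, which is technical. The array held 150921 probes at a median spacing of 90 bp, and 147012 of them (97.4%) lay in 2783 tiled regions that covered 21.57 Mb of the genome. The number of arrays limits the precision, and probe noise ranged from 0.043 in progeny 2 to 0.099 in progeny 7. Positions are on the mm9 build. Genes were not assigned, because the annotation used here is on another build.

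The sex chromosome probes gave the direction of the ratios first. The median over 48 X probes was 0.94 ± 0.055 in the dam, and the median over 3 Y probes was -3.45 ± 0.021, against a male reference. Progeny 5, 6 and 7 had X medians of 0.93, 0.94 and 0.91 and Y medians of -3.24, -3.28 and -3.32. The sire and progeny 1 to 4 lay between -0.04 and 0.02 on X and between -0.02 and 0.05 on Y. The labels give no sex for the progeny.

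The parental changes of copy number divided the litter. A loss on chromosome 16 from 35688022 to 35852776, over 1349 probes and 164.8 kb, had a level of -0.75 ± 0.003 in the sire and -0.01 ± 0.011 in the dam. It stood at -0.75 in progeny 1, -0.68 in progeny 3, -0.70 in progeny 4 and -0.73 in progeny 5, while progeny 2, 6 and 7 were at 0.0. A loss on chromosome 12 from 114943014 to 114972543 (175 probes) was at -0.41 ± 0.027 in the sire and 0.0 ± 0.027 in the dam, and at -0.40, -0.42 and -0.42 in progeny 3, 6 and 7. A shorter loss on chromosome 15 from 68744910 to 68748553 (35 probes) was at -0.83 ± 0.032 in the sire and -0.01 ± 0.025 in the dam, and progeny 3, 5 and 6 were at -0.74, -0.78 and -0.83. The other progeny lay between -0.03 and 0.04 in these regions of chromosomes 12 and 15. The expected level for 1 copy against 2 is -1, and all 3 losses were smaller in size than that.

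A gain on chromosome 4 from 101109089 to 101271085, over 1346 probes and 162 kb, had 3 levels in the litter. The sire and the dam were at 0.49 ± 0.043 and 0.48 ± 0.041. Progeny 1, 5, 6 and 7 were at 0.48, 0.47, 0.48 and 0.50, progeny 2 and 4 were at 0.83 ± 0.024 and 0.78 ± 0.027, and progeny 3 was at 0.0 ± 0.02. As signal relative to the reference, the sire was at 1.40 and the dam at 1.39, and progeny 2 and 4 were at 1.78 and 1.72. The expected log2 level is 0.58 for 3 copies against 2 and 1 for 4 against 2.

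A gain on chromosome 2 ran from 70079530 to 70086801 (70 probes, 7.3 kb). The sire was at 2.86 ± 0.035 and progeny 1, 4, 5, 6 and 7 were at 2.86, 2.49, 2.85, 3.01 and 3.14. The dam, progeny 2 and progeny 3 were at 0.04, -0.03 and 0.06, that is, at the level of the reference. The size of this gain depended on dim probes: progeny 7, at 3.14, was at 1.62 with dim and saturated probes left out and at 1.52 with normexp. On 14 of the 70 probes the reference was not well above background on any of the 18 arrays, so only a bound can be given there. On those probes the carriers were at least 9.23-fold (progeny 4) to at least 10.3-fold (progeny 7) brighter than the reference. The dam, progeny 2 and progeny 3 were likewise not well above background on 22, 27 and 21 of the 70 probes. In the sire and progeny 1, 4, 5, 6 and 7 that number was 0. Gain here means only a higher level than the reference, since the ratio cannot tell more copies in the carriers from fewer in the others. By the rule of 1 shared probe, the dam and progeny 2 also counted as called in this region, through short calls that cover little of it.

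**Figure D1:**
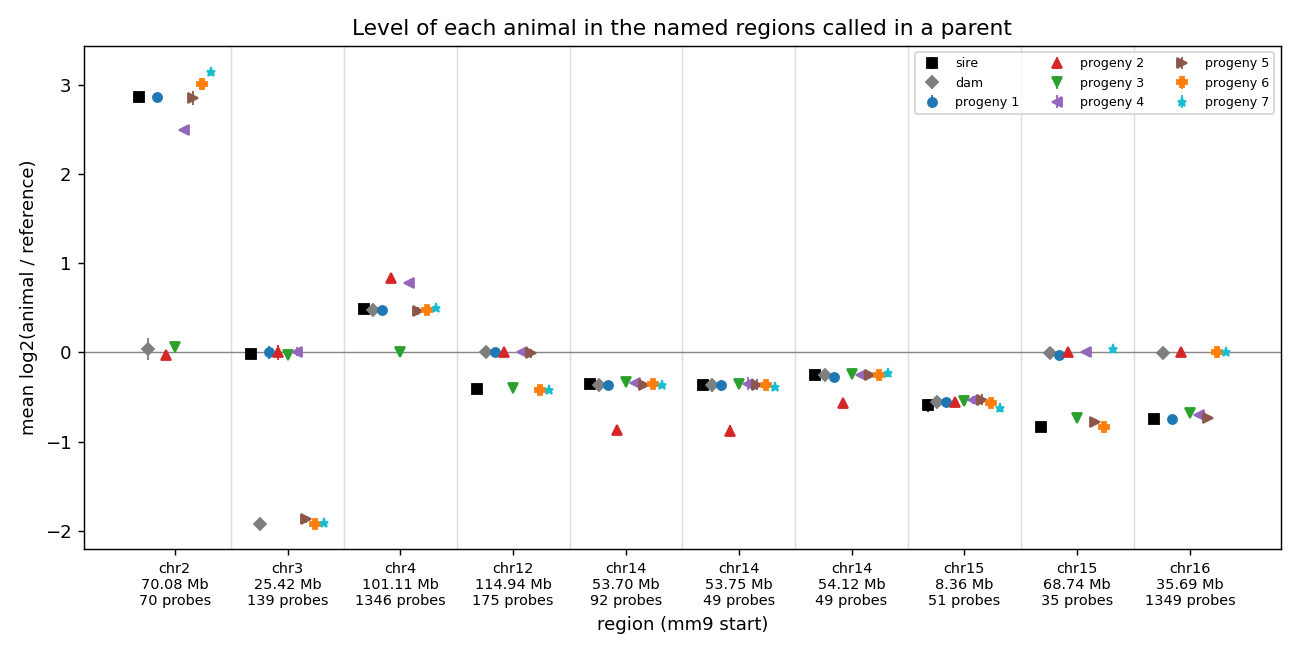
Mean log2(animal/reference) on the y axis for each of the 9 animals in the 10 named regions called in a parent, ordered by chromosome on the x axis (mm9 start), with bars for the SD of both dye orientations. The chromosome 4 gain shows 3 levels, progeny 2 lies below all other animals in the 3 regions of chromosome 14, and the chromosome 15 region from 8356301 is low in all 9 animals.

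In the dam, a loss on chromosome 3 from 25416456 to 25454788 (139 probes, 38.3 kb) was at -1.92 ± 0.012, with the sire at -0.02 ± 0.058. Progeny 5, 6 and 7 were at -1.87, -1.92 and -1.91, and progeny 1 to 4 lay between -0.03 and 0.01. A loss on chromosome 14 from 61799247 to 61816808 (-0.33 ± 0.043 in the dam) and a gain on chromosome 17 from 36896662 to 36899652 (0.30 ± 0.081 in the dam) stood in the same 3 progeny. Their levels were -0.32, -0.33 and -0.34 for the chromosome 14 loss and 0.31, 0.31 and 0.30 for the chromosome 17 gain. The dam and progeny 5, 6 and 7 are also the only animals with an X median above 0.9, with Y medians of -3.45 to -3.24. All 3 changes thus followed the sex chromosome ratios. For the chromosome 14 loss and the chromosome 17 gain, inheritance from the dam cannot be told apart here from a signal of the sex chromosomes. On chromosome 3, progeny 5, 6 and 7 lay below -1, the level expected for 1 copy against 2. With the sire at the level of the reference, a loss of 1 copy of 2 through the dam would not go below -1. These levels argue against such a loss as the whole of the chromosome 3 change.

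Whether a parental change reached about 50% of the litter was tested for the 196 calls made in exactly 1 parent, 71 in the sire and 125 in the dam. A total of 104 calls differed from that share in the two-sided exact binomial test (adjusted p = 0.0294), and all 104 had 0 carriers among 7 progeny. With 7 progeny the smallest p this exact test allows is 0.0156, and a call with 1 to 6 carriers cannot pass. With an absolute mean of at least 0.4, no call passed after adjustment. Calls with 0 carriers share 1 p, so they pass or fail together, and this does not show that none remained. Of the 104, 66 were gains of the dam, and over 56 of these the sire, on the same slide, was also above the reference. Progeny 1 and 2, which shared another slide, were both below the reference over 58 of the 66. The medians over the 66 were 0.33 in the dam, 0.11 in the sire, -0.18 in progeny 1 and -0.21 in progeny 2. The dye profile, which holds no copy number signal, gave 67 calls in the sire and 87 in the dam, without the orientation check. The copy number profile, with that check, gave 79 and 134. The rest of the 104 shared this profile less. The other parent had the same sign over 3 of 17 gains and 3 of 5 losses of the sire and 2 of 16 losses of the dam. Progeny 1 and 2 were both on the other side over 3, 0 and 5 of them. Other shifts stood in several animals. Over the 16 losses of the dam the medians were -0.32 in the dam, 0.31 in the sire and 0.38 in progeny 5. Over the 17 gains of the sire they were 0.30 in the sire and 0.20 in progeny 5. Among the calls of 20 probes or more, all had carriers. Gains of the dam over 10 probes of chromosome 3 from 66008939 and 12 probes of chromosome 9 from 40544655 had 0. When calls had to share 50% of their probes, the chromosome 2 gain of the sire had 5 carriers among the 7 progeny and the chromosome 16 loss had 4. The chromosome 14 losses called from 54116505 in the sire and from 54380321 in the dam had 2 and 3. Neither is a loss of 1 parent only. The sire and the dam were both at -0.25 in the first, and at -0.24 and -0.26 in the second. All 7 progeny were also lower than the reference in both, so the carriers there depend on the call limit of 0.25 and do not show transmission. The losses of chromosomes 12 and 15 had 3 carriers each, as did the 3 changes of the dam on chromosomes 3, 14 and 17. These 3 changes of the dam had the same carriers, and they belong to a set of 21 regions on 15 chromosomes with exactly these carriers, so they are not 3 independent cases of transmission. The carriers are the progeny with an X median above 0.9, so transmission itself is not shown for these changes.

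Progeny calls without a parental call were next. The largest was a gain on chromosome 14 in progeny 2 and progeny 6. Its 4 tiled blocks, with 1101 probes, lay between 87494559 and 87693792, a span of 199.2 kb. Progeny 2 was at 0.51, 0.50, 0.48 and 0.49 in the blocks, in order, and progeny 6 at 0.49, 0.53, 0.49 and 0.50, with SDs of the orientations of at most 0.022. The sire and progeny 1, 3, 4, 5 and 7 lay between -0.02 and 0.05. No call was made in the dam, but the level of the dam was 0.17, 0.22, 0.18 and 0.18, above the highest single orientation of those 6 animals (0.02, 0.06, 0.03 and 0.03). Under the rule that a parental score of at least 4 counts as present, this gain was no longer absent from the parents.

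**Figure D2:**
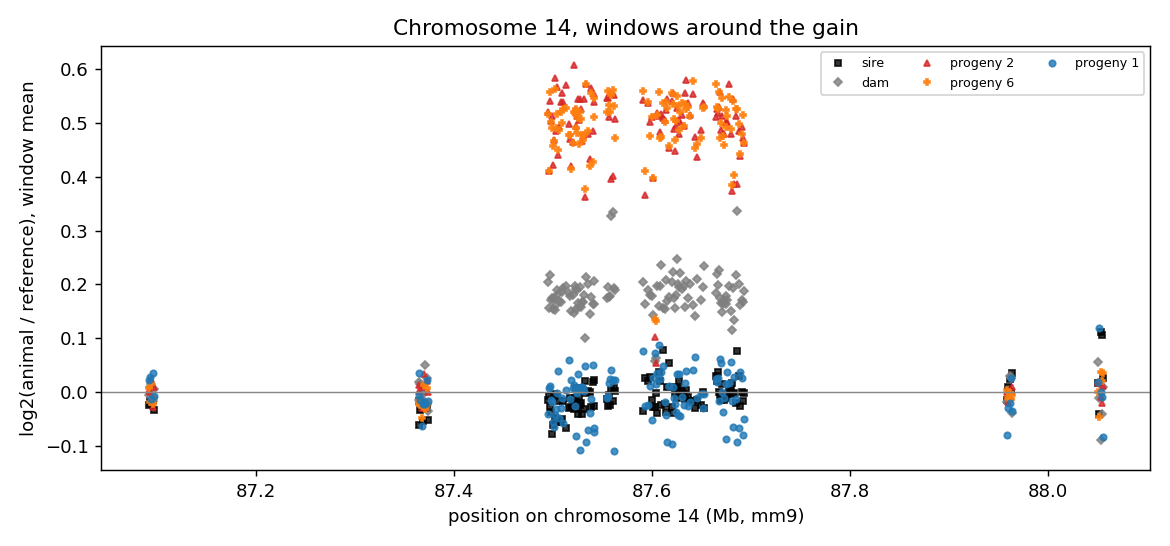
Log2(animal/reference) on the y axis, as means of windows of up to 10 probes, against position on chromosome 14 (Mb, mm9) on the x axis, for the sire, the dam and progeny 1, 2 and 6. By block means, progeny 2 and 6 lie at 0.48 to 0.53 between 87494559 and 87693792 and the dam at 0.17 to 0.22, though single windows depart from this, and the means of the 5 animals over the tiled regions on either side lie between -0.04 and 0.04.

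Also on chromosome 14, 9 tiled blocks with 587 probes between 53408430 and 54390579 were lower than the reference in every animal. Progeny 2 was lowest in each, at -0.51 to -0.88, whereas the other 8 animals lay between -0.39 and -0.20. In the block from 53701249 to 53723304 (92 probes), progeny 2 was at -0.87 ± 0.036, and the other 8 averaged -0.35 ± 0.01 (SD, n = 8). In the block from 53960326 to 53998171 (180 probes), progeny 2 was at -0.51 ± 0.012 and the other 8 averaged -0.23 ± 0.01 (SD, n = 8). Because the level of the other animals lies close to the minimum of 0.25 for a call, some of these blocks counted as called in a parent and others did not. The loss was interrupted: between 54073781 and 54076286, inside the span, 2 windows lay at -0.017 and 0.012 in progeny 2 and between -0.046 and 0.055 in the other 8 animals. In the tiled regions that flank the span, from 52750103 and from 54588200, progeny 2 was at -0.02 and 0.0.

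**Figure D3:**
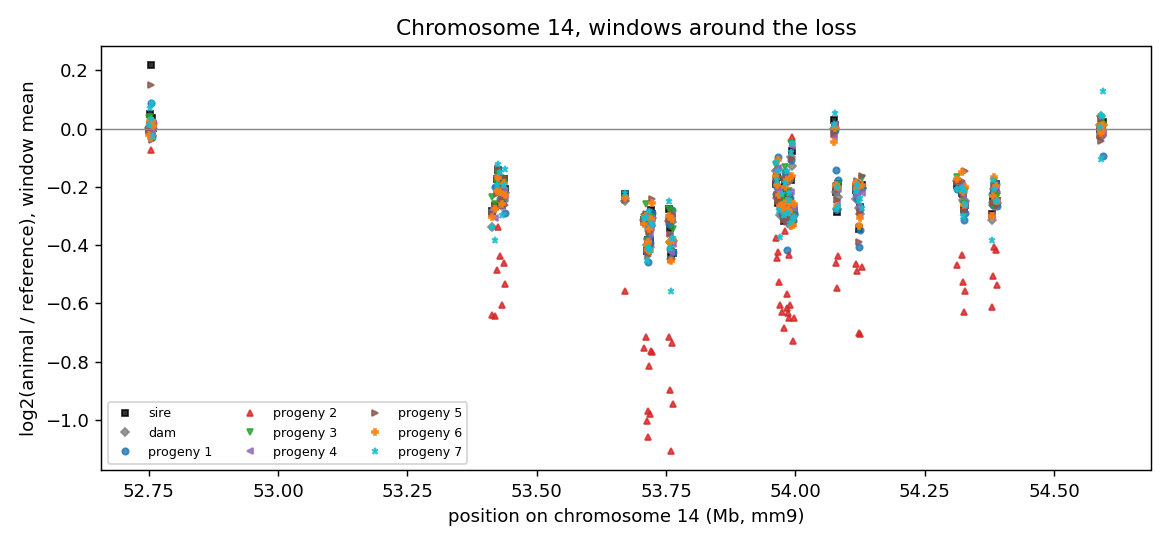
Log2(animal/reference) on the y axis, as means of windows of up to 10 probes, against position on chromosome 14 (Mb, mm9) on the x axis, for all 9 animals. The block mean of progeny 2 lies below those of the other 8 in each of the 9 blocks, though not in every window, and the animals lie between -0.02 and 0.06 on average in the first and last tiled regions drawn.

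In total 246 calls of the 7 progeny were absent from both parents (exact 95% Poisson interval 216.2 to 278.7, counting error only), 100 gains and 146 losses. Without progeny 7, the noisiest animal, the number was 161, and the balance turned to 97 gains and 64 losses. Without progeny 5 it was 43 gains and 137 losses. The number also moved with the processing: it was 99 with normexp, 632 with only the Cy5 array, 117 at a score floor of 8, 85 with at least 5 probes and 85 with a mean of at least 0.4. Both parents lay on 1 slide that held no progeny, so the count compares across slides. Over 71 of the 246 calls both parents were on the other side of the reference, among them 27 losses of progeny 7, which lay alone on a slide, and 17 losses of progeny 1 and 15 of progeny 2, which shared one. Progeny 7 held 85 of them, progeny 5 held 66, progeny 1 held 38, progeny 2 held 31, progeny 6 held 16, and progeny 3 and 4 held 5 each. Of the 246 calls, 175 rested on 3 probes, and 12 rested on 10 probes or more. All 12 belonged to progeny 2 or 6. Of these, 8 belong to the chromosome 14 gain, 3 belong to the chromosome 14 blocks with the larger loss in progeny 2, and the last is a loss on chromosome 9 from 40544655 to 40545587 (11 probes) at -0.26 in progeny 2. The dam was at 0.34 and the sire at 0.12 over the same chromosome 9 probes, so the parents lay on the other side of the reference. When a parental score of at least 4 counted as present, 158 of the 246 remained, and 1 of the 158 had 10 probes or more. The other regions that the naming rule gave were short. A gain on chromosome 12 from 63877453 to 63878173 (5 probes) was at 0.34 ± 0.058 in progeny 2, and at -0.016 when dim probes were left out. A loss on chromosome 16 from 65460168 to 65460385 (3 probes) was at -0.57 ± 0.254 in progeny 6, at -0.083 when dim and saturated probes were left out and at -0.212 with normexp.

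Over the 9 animals the scan made 740 calls, 347 gains and 393 losses, which merged into 477 regions, 349 of them called in 1 animal. Without progeny 7 the balance turned to 336 gains and 253 losses, and without progeny 5 it was 229 gains and 342 losses. The sire had 79 calls and the dam 134, and the progeny had from 18 (progeny 3) to 169 (progeny 5). Calls of 3 to 5 probes made up 81.8%. The scan on the dye profile, in which copy number cancels and no orientation check applies, made 777 calls. Only 14 of them had 10 probes or more, against 95 such calls in the copy number profile. The probe noise of the dye profile was 0.086 to 0.114, against 0.043 to 0.099, so these counts are not like for like. When the scan itself required at least 10 probes, a limit chosen after seeing the data, the counts were 48 and 120. With probe order shuffled within chromosomes the scan made 4121.5 calls on average, since the shuffle scatters the probes of the long changes. Without the probes of the long changes it made 377.4, and none of 10 probes or more. This last version was chosen after seeing the data. A shuffle breaks up every run of neighbouring probes, so the absence of long calls there does not bear on shifts shared by neighbours. Across probes, the orientations of an animal correlated between -0.129 (progeny 3) and 0.275 (progeny 5), with Spearman rho between -0.535 and 0.03. These correlations are across probes, which are not independent replicates.

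Differences between the reference and the mean of the 9 animals were tested over 14477 windows of up to 10 probes with limma. In this test 180 windows passed (Benjamini-Hochberg adjusted p under 0.05 and a mean of at least 0.25 in size). Of these, 136 were higher and 44 were lower than the reference. Without progeny 7, the noisiest animal, 135 were higher and 72 were lower. The higher ones were 134 windows of the chromosome 4 gain and 2 of the chromosome 2 gain. Of the lower ones, 39 lay in the chromosome 14 blocks between 53408430 and 54390579, and 5 in a loss on chromosome 15 from 8356301 to 8360893. That loss (51 probes, 4.6 kb) was at -0.59 in the sire, -0.56 in the dam and -0.53 to -0.62 in the progeny, a mean of -0.56 ± 0.03 (SD, n = 9). A 5-probe gain on chromosome 13 from 95705166 to 95707908 was the only other region called in all 9 animals besides 2 of the chromosome 14 blocks, with a mean of 0.36 ± 0.05 (SD, n = 9). The chromosome 4 windows with the smallest adjusted p began at 101109952, 101110995, 101112273, 101113754 and 101115059, with means of 0.43 to 0.55 (limma, adjusted p = 0.00145 each). They are the first by position of 86 windows with that adjusted p, and in all 5 progeny 3 lay between -0.014 and 0.011. The chromosome 14 windows with the smallest adjusted p began at 54381604, 54388905, 54379846, 53408430 and 53984561, with means of -0.27, -0.28, -0.33, -0.33 and -0.33 (limma, adjusted p = 0.000736 to 0.000773, lower in 9 of 9 animals). The last 2 are the first by position of 4 windows with an adjusted p of 0.000773. The adjusted p does not rank windows by the spread between animals alone. Limma with trend moves the variance of each window toward that of windows of similar mean. In the chromosome 15 window from 8356301 the 9 animals lay between -0.634 and -0.558 (limma SE 0.1218, adjusted p = 0.0298). In the chromosome 4 window from 101109952 they lay between -0.014 and 0.723 (limma SE 0.0585). The reference is 1 mouse, so the test leaves out its own error. The 9 animals are parents and their offspring, so they are not independent replicates, and the adjusted p does not allow for that. A window can also pass on the mean without a difference in every animal. In the chromosome 2 window from 70078672 the dam was at -0.112, progeny 2 at 0.084 and progeny 3 at 0.036. With only 1 of the dye orientations, 310 (animal in Cy5) or 321 (animal in Cy3) windows passed, and the lower ones rose to 172 and 184.

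No window separated the litter from the parents in the test. Of the 14477 windows, 0 passed the limma test of 7 progeny against 2 parents, and 332 had an unadjusted p under 0.05. Without the dam or without the sire, the parents are 1 animal and the spread comes only from the progeny, so those fits are not counted. The parents shared a slide with each other and with no progeny, so no slide holds both generations. With the slide as a random block 0 windows passed and 99 had an unadjusted p under 0.05. Both 332 and 99 are below a share of 0.05 of the 14477 windows, the share expected with no difference. Between the parents, which allow no test, the median absolute difference per window was 0.024. The sire was above the dam by at least 0.25 in 37 windows and below by as much in 170. The 170 include windows of the chromosome 16 loss (1349 probes, -0.75 in the sire and -0.01 in the dam). The 37 include windows of the chromosome 3 loss (139 probes, -0.02 in the sire and -1.92 in the dam).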

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

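All tests of explanations in this part were chosen after the result was seen. Over 28 quantities of the 7 progeny (noise, numbers of calls, correlation of the orientations, sex chromosome medians and the levels of the named regions), 7 had a progeny far from the other 6. Chance alone gives about 1 in 20 for quantities chosen without regard to the values, which does not hold here, since the regions were named by their scores. All 7 were levels of progeny 2 in neighbouring blocks of chromosome 14, so they are not independent. The gap to the nearest progeny was at least 0.853 of the range in each.

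The levels of progeny 2 were -0.52 in the block from 53408430 (others -0.24 to -0.21), -0.56 from 53661805 (others -0.25 to -0.22), -0.87 from 53701249 (others -0.36 to -0.33) and -0.88 from 53754763 (others -0.39 to -0.35). They were -0.51 from 53960326 (others -0.25 to -0.21), -0.57 from 54116505 (others -0.28 to -0.23) and -0.54 from 54304342 (others -0.25 to -0.20). A difference of the reference mouse alone would put all 9 animals at 1 level, and progeny 2 lay below the lowest of the other 8 by at least 0.25 in each block. The distance of progeny 2 from the other progeny is also what flagged these levels, so it is not separate evidence. A slide effect would shift progeny 1, which shared the slide, and progeny 1 lay within 0.04 of the median of the other animals. The loss of signal in progeny 2 was 2.05 times that of the other animals (median over the 8 blocks of 20 probes or more, range 1.91 to 2.11), although the level of the blocks varied and 2 windows inside the span, from 54073781 to 54076286, were near 0 in all 9 animals. Single windows inside the blocks also departed from this. In the window from 53992060 progeny 2 was at -0.027, the highest of the 9 animals. From 53990221 it was at -0.277, above progeny 6 at -0.336. A candidate explanation of the block means is 2 doses in progeny 2 of a loss of which the sire, the dam and 6 progeny have 1, with probes that match several places setting the level of each block. If both parents had 1 dose, the chance that none of 7 progeny is without the loss is 0.133, and an added loss in progeny 2 on top of a difference of the reference stays open.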

How the results depend on the processing

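The number of calls (740) ranged from 506 to 826 under the other centrings, background correction, score floors, gaps and the filter on dim probes. It was 1956 with only the Cy5 array, 1249 with only the Cy3 array, 320 with at least 5 probes, 261 with a mean of at least 0.4 and 120 with at least 10 probes. The calls in the dye profile (777) became 1701 at a score floor of 5, 183 at a floor of 8, 442 with at least 5 probes, 157 with a mean of at least 0.4 and 48 with at least 10 probes. They have no value for a single orientation. The progeny calls absent from both parents (246) became 99 with normexp, 632 with only the Cy5 array, 117 at a score floor of 8, 85 with at least 5 probes, 85 with a mean of at least 0.4, 19 with at least 10 probes and 158 when a parental score of at least 4 counted as present. Parental calls that passed the test against a share of 50% (104) became 44 with at least 5 probes, 0 with a mean of at least 0.4 and 12 with at least 10 probes. The limit of 10 probes was chosen after seeing the data. The windows that differed from the reference (180) became 310 with only the Cy5 array, 321 with only the Cy3 array, 363 with windows of 5 probes and 95 with windows of 20, where the number of windows tested also changes. The cause of the other changes was not tested. Leaving out each animal gave 571 to 722 calls, 161 (without progeny 7) to 291 (without the sire) absent calls, and 170 to 207 windows against the reference (lower windows 72 without progeny 7, against 44). For progeny against parents, every setting that kept both parents gave 0 windows. Fits without the sire or the dam are not counted there, because 1 parent gives no spread.

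Of 190 values of the named windows under the alternatives, 187 stayed past the threshold and 3 did not. Of 147 values of the named regions, 128 moved by no more than the SD of the orientations (or 0.005, where that is larger), 18 moved by more with the same sign, and 1 changed sign, the chromosome 12 gain from 63877453 in progeny 2, at -0.016 without dim and saturated probes. GC correction, removal of probes with several matches and the gene list overlap were not run. No paired analysis was possible because the replicate number names a single animal.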

Other observations

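All tests of explanations in this part were chosen after the result was seen. A set of 21 regions was called in exactly the dam and progeny 5, 6 and 7, the animals whose X median was above 0.9. Besides the regions of chromosomes 3, 14 and 17 given above, they were short, with a median of 5 probes over all 21. Examples are a loss on chromosome 3 from 132549207 (-0.69 in the dam, -0.60, -0.62 and -0.69 in progeny 5, 6 and 7) and a loss on chromosome 6 from 104241190 (-0.50 in the dam, -0.42, -0.44 and -0.42 in these progeny). A gain on chromosome 12 from 8798600 was at 0.47 in the dam and at 0.46, 0.48 and 0.35 in these progeny.

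Independent autosomal variants of the dam would reach different progeny, yet these 21 regions lay on 15 chromosomes, and none of the other 125 sets of 4 animals had more than 1 region. That count is the pattern itself, so it is not a separate test of it. A slide effect would reach the sire, which shared the dam's slide, and the sire's median absolute level over the 21 regions was 0.02. The regions were chosen for having no call in the sire, so this level is not an independent test. A candidate explanation is that these probes also match a sex chromosome. The 4 animals were lower in 19 regions and higher in 2, but the probe sequences that would test this were not used here, so it stays open.

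The level of the dam in the chromosome 14 gain of progeny 2 and 6 was the second pattern weighed here. A dye or hybridisation error of 1 array would leave the other array near 0, and the lowest orientation of the dam over the 4 blocks was 0.17, against at most 0.06 in the other 6 animals. A wave along the chromosome would raise the neighbours, and the 2 next tiled regions on either side were at most 0.01 from 0 in the dam. DNA of progeny 2 in the dam's sample would bring the Y ratio to -1.33, and it was -3.45; DNA of progeny 6 would bring the chromosome 2 level to 1.72 (0.65 without dim probes) and the chromosome 15 level from 68744910 to -0.22, and they were 0.04 and -0.01. The excess signal of the dam was 0.33 of that of progeny 2 and 6 over the blocks, from 0.31 to 0.39, which is consistent with the hypothesis of a gain in part of the dam's cells, found and tested on the same data; DNA of an animal outside the family stays open.

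A loss and a gain were called over nearly the same 11 or 12 probes of chromosome 9 from 40544655, at -0.26 in progeny 2 and 0.33 in the dam. A 10-probe region of chromosome 3 from 66008939 to 66009710 was at 0.35 in the dam and at -0.25 and -0.24 in progeny 1 and 2. Progeny 1 and 2 shared a slide.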
